A study of Mus musculus with 6 samples.

How the data were processed

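RNA was taken from humeral bone of C57BL/6 mice at postnatal day 6 after the marrow had been flushed out with PBS, per the labels' protocols. From 50 ng of RNA with an integrity number above 6.7, poly(A)-selected directional libraries (NEBNext Ultra II) of 375 to 390 bp were made and sequenced on an Illumina MiSeq. The submitters' processing notes name TopHat, Cufflinks and the mm10 build, without versions or roles. The counting program, its use of strand, the way size factors were set and the authors' test are not given in the sources used here.

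The authors deposited 1 table of 23420 genes, with each gene's exon blocks, a value per library, the group means, a log2 fold change, a p-value and a q-value, per the file headers. The values per library are a signal that the authors made from read counts, each library divided by 1 size factor, as the values themselves show. In each library 100% of the values are whole multiples of the value of 1 read (tolerance 0.001 reads), so whole reads were recovered. In 2 control libraries (replicates 1 and 3) the value of 1 read lies within 1% of 1, so the test for steps is weaker there, but their values are not rounded. The recovered reads sum to 1441152 to 1714770 per library. Intervals and floors from reads cover counting error only, since PCR copies are not independent molecules. The log2 fold change that the authors deposited was not used. Their q-value was used to count their calls, and it is named as the authors' deposited table wherever printed.

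The plan fixed before the data were examined assumed FPKM and a limma test, with edgeR instead if the table held whole read counts. The table holds normalized counts, from which whole reads could be recovered. The planned limma test was kept and run on log2(normalized count + 1), for genes with a mean normalized count of at least 1 over the 6 libraries (14438 genes). Fold changes are on that scale, which understates the change of genes with few reads, and mean ± SD values are normalized counts. limma 3.58.1 in R 4.3.3 was fitted to all 6 libraries with genotype as the only term and a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Tfam was also tested by an exact two-sided permutation test over all 20 arrangements. Gene lists (27, fixed before the data were examined) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists with at least 5 tested members. Each list's members were counted past the threshold over all genes and adjusted over the list alone. A gene at 0 in every library of a group was also placed at its bound, which moved the median of the B lymphoid list only. Another 8 lists were added after seeing the data and appear only among the other observations.

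The genes named follow a rule fixed before the data were examined. It takes Tfam, the 6 largest rises and 6 largest falls among called genes whose groups do not overlap (predicted genes passed over), the 3 members with the smallest p of each main list and the 1 of each list of other cell types, always Tnfsf11, Tnfrsf11b, Col1a1 and Bglap. Other genes are said to be chosen after their values were seen. Of the 94 genes named by the rule or so chosen, 3 share exon bases with a gene on the opposite strand in the table. Atf5 shares 64 of 1993 bases with Nup62 and 82 with Nup62-il4i1, Ddit3 68 of 871 with Mars, and Scpep1 96 of 2074 with 4930405P13Rik.

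The alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean of at least 5, quantile normalization, rescaling by the median of ratios, the replicate number as a block, leaving out each library in turn, a robust limma fit, camera with the correlation estimated per list, and the authors' q. After seeing the data, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the reads recovered from all 6 libraries were added. edgeR called 1786 genes and DESeq2 1138.

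The scripts were tested on simulated data made from the real means and library sizes. Of genes changed by a log2 fold change of 1, limma recovered 62.9%, and of those changed by 2, 84.7%, among 14277 genes tested, with 12 false among 164 calls. Of 25 simulated lists without change, 0 were called, and 1 of 1 changed list was. Those lists had no correlation between genes. Figures were drawn with matplotlib.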

Results

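Poly(A) RNA from the humerus of C57BL/6 mice at postnatal day 6 was sequenced in 3 control libraries and 3 libraries from mice lacking Tfam in the limb mesenchyme (Tfam cKO). Tfam, mitochondrial transcription factor A, packages mitochondrial DNA and is needed to transcribe it, and the Prx1-Cre driver acts in the mesenchymal cells that form the limb skeleton. The bones had been flushed with PBS to remove marrow before RNA was extracted. Each library held between 1441152 and 1714770 reads assigned to genes, a modest depth at which a gene with a few reads is measured loosely. Libraries of the same group correlated at r = 0.950 to 0.967 across genes on the log2 scale, and libraries of different groups at 0.913 to 0.956. No 2 libraries agreed within sampling noise. The labels do not say whether each library came from a separate animal, so p-values of single genes measure the spread between these libraries. The camera p-values of gene lists at the preset correlation weigh members against all other genes and do not measure that spread.

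The comparison of the 2 genotypes asks how the developing bone's transcriptome differs when its mesenchymal cells lose Tfam. Tfam itself was lower in the Tfam cKO humerus, at 40.6 ± 10.8 normalized reads against 70.7 ± 8.75 in controls (SD, n = 3 each), or 57.5% of the control mean. The cKO values were 28.1, 46.1 and 47.6, all below the control values of 61.3, 72.1 and 78.6. The log2 fold change was -0.81 ± 0.21 (SE), with a limma adjusted p of 0.0246, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Tfam lies on chromosome 10, minus strand, at 71225477 to 71238044 (mm10), with 7 exon blocks in the deposited table. Which part of the gene is deleted is not given in the sources used here, and the bone also holds cells outside the Prx1-Cre lineage. The direction held without any 1 library, but the adjusted p rose to 0.0503, 0.0704 and 0.107 without Control replicate 1, 2 or 3 and to 0.0748 without Tfam cKO replicate 1, and it was 0.0582 with DESeq2, a fit chosen after seeing the data.

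Of 14438 genes tested, 1795 differed at an adjusted p under 0.05, with 927 higher and 868 lower in Tfam cKO. The largest rises were in Cdsn, which encodes an adhesion protein of cornified skin (from 2.95 ± 3.02 to 360 ± 67.1 normalized reads), Avil, an actin-binding protein (4.61 ± 2.18 to 199 ± 31.3), and Trib3, a pseudokinase induced in the integrated stress response (4.89 ± 0.18 to 167 ± 38.8). Klk4, a secreted protease of enamel formation, had no read in any control library and 52 in the Tfam cKO libraries, and was at least 18.2-fold higher against a floor of 3 reads over the group. Slc7a3, a transporter of cationic amino acids, rose from 1.29 ± 0.50 to 39.7 ± 9.84, and Col10a1, the collagen of hypertrophic cartilage, from 70.4 ± 51.0 to 926 ± 400. The largest falls were led by genes of the B lineage. Rag1, a recombinase of antigen receptor genes, fell from 116 ± 37.1 to 5.98 ± 3.64 (log2 fold change -4.19 ± 0.38 SE, adjusted p = 4.45e-05). Vpreb1 (log2 fold change -3.39) and Igll1 (-3.27), the surrogate light chain of the pre-B cell receptor, fell with the lymphoid transcription factor Irf4 (-3.28) and the plasma cell chaperone Mzb1 (-3.24). A2m, a protease inhibitor, went from 48 control reads to 2, a ratio of 22.9 with a 95% counting interval of 6.01 to 195. Among the 1795 genes, 1781 had no overlap between the libraries of the 2 groups, as did 4628 of all tested genes, where chance gives 10% or 1443.8. The count of 1795 fell to 891 without Control replicate 1 (875 of them among the 1795), 1103 without Control replicate 3, 1166 without Tfam cKO replicate 1 and 1090 without Tfam cKO replicate 3. The authors' deposited table called 1551 genes at q under 0.05, of which 1510 were among the 1795, all in the same direction, from the same 6 libraries.

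**Figure D1:**
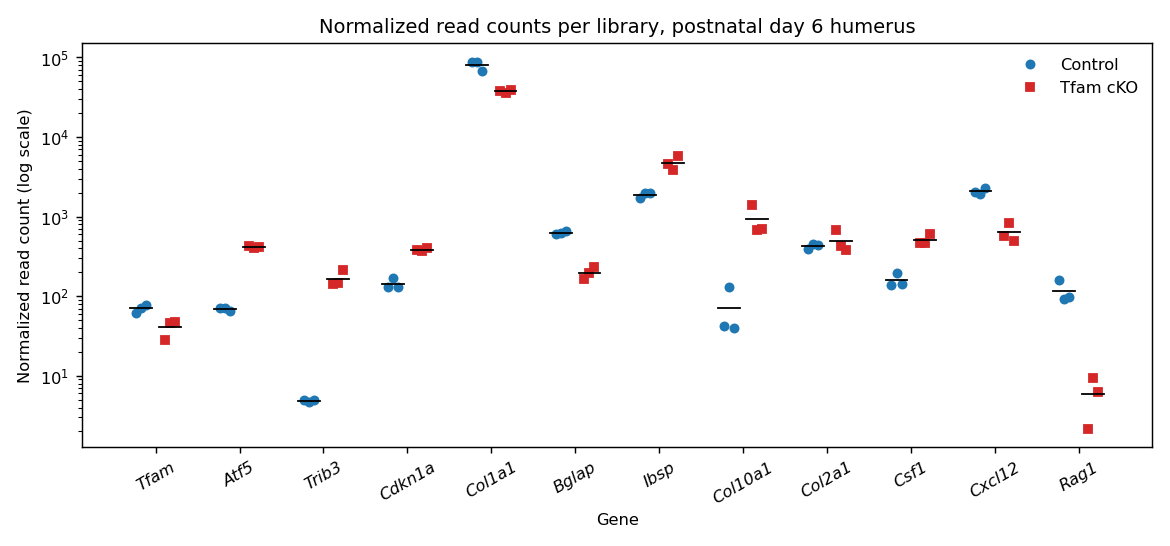
Normalized read counts (log axis) of 12 genes in the 3 control (circles) and 3 Tfam cKO libraries (squares), with a line at each group's mean. Atf5, Trib3, Cdkn1a, Ibsp, Col10a1 and Csf1 were higher in every Tfam cKO library than in every control library. Tfam, Col1a1, Bglap, Cxcl12 and Rag1 were lower in every Tfam cKO library, while Col2a1 overlapped. Quantile normalization put Col1a1 at a log2 fold change of 0.02, but it gives all libraries the same highest values and so cannot show this fall.

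Targets of the integrated stress response rose together in Tfam cKO bone. This programme, run by the transcription factor Atf4, induces amino acid synthesis and transport. Of 30 members tested, 24 were higher and 0 lower (27 and 0 when adjusted over the list alone), with a median log2 fold change of 0.98. Atf5, a transcription factor of the same family, rose from 69.1 ± 2.98 to 412 ± 14.7 normalized reads (log2 fold change 2.56 ± 0.11 SE, adjusted p = 9.17e-08). Phgdh, the first enzyme of serine synthesis, rose from 114 ± 5.28 to 299 ± 39.6 (1.37 ± 0.12, adjusted p = 3.15e-05). Atf4 itself (0.57), Ddit3 (1.46) and Chac1 (2.69), chosen after their values were seen, rose as well. The list as a whole was higher by limma's camera test (adjusted p = 3.90e-24), with adjusted p = 0.138 with an estimated correlation.

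Of 19 genes listed as p53 targets or markers of senescence, 9 were higher and 0 lower (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.60. Of the 19, 3 are also on another list, 2 of them on that of the stress response. Cdkn1a, the cell cycle inhibitor p21, rose from 143 ± 22.6 to 382 ± 15.8 normalized reads (log2 fold change 1.42 ± 0.12 SE, adjusted p = 2.87e-05), and the proapoptotic genes Bax (0.86) and Phlda3 (1.19) rose with it. The camera test gave an adjusted p of 2.53e-05, and adjusted p = 0.138 with an estimated correlation. The number of higher members was 5 without Control replicate 1 and 5 without Tfam cKO replicate 1.

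Cell cycle genes were lower. Of 30 tested, 20 fell and 0 rose (27 and 0 adjusted over the list alone), with a median log2 fold change of -0.55. The mitotic kinesin Kif11 fell from 336 ± 59.3 to 176 ± 14.1 normalized reads (-0.92 ± 0.13 SE, adjusted p = 8.52e-04), and the replication helicase subunit Mcm7 (-0.64) and the topoisomerase Top2a (-0.65) fell with it. The camera test gave an adjusted p of 2.39e-15, and adjusted p = 0.445 with an estimated correlation. The number of lower members was 9 without Control replicate 1 and 11 without Tfam cKO replicate 1. Markers of blood-forming cells, given below, were lower in the same libraries.

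Of 74 subunits of the respiratory chain encoded in the nucleus, 4 rose and 0 fell, with a median log2 fold change of 0.21, and 0 passed when adjusted over the list alone. Uqcrq, of complex III (0.49 ± 0.12 SE, adjusted p = 0.0171), Cox6b1, of complex IV (0.44 ± 0.12, adjusted p = 0.0298), and Atp5c1, of the ATP synthase (0.36 ± 0.09, adjusted p = 0.0246), were among the 4. The camera test on this list gave an adjusted p of 2.52e-07, and adjusted p = 0.445 with an estimated correlation. With each library's trend with exon length removed, as described below, the median was 0.11 and 1 subunit was higher. Leaving out 1 library gave 0 higher subunits (Control replicate 1 or 3), 1 (Tfam cKO replicate 1 or 3), 2 (Tfam cKO replicate 2) or 8 (Control replicate 2). Among 16 mitochondrial chaperones and proteases, 3 rose and 0 fell (6 and 0 adjusted over the list alone), led by the chaperone Hspa9, from 431 ± 38.4 to 1171 ± 128 normalized reads (1.44 ± 0.11, adjusted p = 1.01e-05), with the protease Lonp1 (0.60) and the cochaperone Dnaja3 (0.49). The list's camera adjusted p was 0.00817, and adjusted p = 0.231 with an estimated correlation, and its median of 0.28 was 0.17 without Control replicate 1. The Dnaja3 call ended without any 1 library other than Control replicate 2, at adjusted p from 0.0590 to 0.107. Of 76 mitochondrial ribosomal proteins, 1 rose, Mrps16 (0.75, adjusted p = 0.0246), and 0 passed when adjusted over the list alone. Their median was 0.16, with a camera adjusted p of 0.0198, and adjusted p = 0.445 with an estimated correlation. Without Tfam cKO replicate 3 that median was 0.10 and the list no longer passed. Mrps16 lost its call without any 1 library other than Control replicate 2, at adjusted p from 0.0548 to 0.0909. With DESeq2 the calls of Uqcrq, Cox6b1, Atp5c1, Dnaja3 and Mrps16 ended (adjusted p = 0.0714, 0.0761, 0.0742, 0.191 and 0.122). edgeR, fitted to the same reads, changed no call and no direction among the 90 named genes it tested.

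Among 15 genes of mitochondrial DNA maintenance and transcription, Tfam was the only one past the threshold, also adjusted over the list alone. Rrm2b, a ribonucleotide reductase subunit (log2 fold change -0.54, adjusted p = 0.229), and Polrmt, the mitochondrial RNA polymerase (0.41, adjusted p = 0.233), did not pass. The 13 mRNAs encoded by mitochondrial DNA were not analysed here, since the table used has 0 rows on that chromosome. Of 20 genes of glycolysis and lactate transport, 2 were higher and 3 lower (3 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.251). The hexokinases moved in opposite directions, Hk2 rising from 46.2 ± 2.47 to 90.9 ± 3.94 normalized reads (0.96 ± 0.14 SE, adjusted p = 0.00113) and Hk1 falling from 353 ± 42.8 to 236 ± 24.1 (-0.58 ± 0.12, adjusted p = 0.00724). The lactate transporter Slc16a1 fell (-0.60, adjusted p = 0.0172), a call that ended without Control replicate 1 (0.0903), Tfam cKO replicate 1 (0.0648) or Tfam cKO replicate 3 (0.0629), and leaving out any 1 library gave 1 or 2 higher and 1 or 2 lower genes in this list. Of 19 hypoxia response genes, 2 were higher and 1 lower, with the same counts adjusted over the list alone and a camera adjusted p of 0.202. They were Mif, a cytokine (0.61, adjusted p = 0.00831), Vegfa, an angiogenic factor (0.50, adjusted p = 0.0443), and P4ha1, a collagen prolyl hydroxylase (-0.40, adjusted p = 0.0234). The Vegfa call ended without any 1 library other than Tfam cKO replicate 2, at adjusted p up to 0.156, and that of P4ha1 without any other than Tfam cKO replicate 1, at up to 0.0844. Both ended with DESeq2 (0.0728 and 0.0739), and that of Vegfa also after quantile normalization (0.0534) or with pseudocount 0.1 (0.0537). None of 27 interferon-stimulated genes passed, also adjusted over the list alone, with Oas1a (1.22), Ifi44 (1.68) and Ifih1 (-0.61) having the smallest p-values and a camera adjusted p of 0.799. Their median of -0.16 (-0.28 to -0.02 with any 1 library left out) and mean of 0.03 differed in sign.

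Genes of the bone-forming osteoblast split in direction. Type I collagen, the main protein of bone matrix, took 10.3% ± 0.94 of the reads in controls and 4.71% ± 0.21 in Tfam cKO (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Col1a1 on chromosome 11 fell from 80953 ± 11342 to 37653 ± 1451 normalized reads (log2 fold change -1.09 ± 0.23 SE, adjusted p = 0.00738). After quantile normalization the difference was 0.02. That method gives all libraries the same highest values, and Col1a1 and Col1a2 hold the 2 highest in all 6 libraries, so it cannot show this fall. Bglap, which encodes osteocalcin, a protein of mature osteoblasts, fell from 629 ± 24.9 to 197 ± 34.7 (-1.68 ± 0.12, adjusted p = 9.51e-06), as did Bglap2 (-1.34), and the 2 are near-identical neighbours whose reads may be split between them. Ibsp, a sialoprotein that seeds mineral, rose from 1890 ± 163 to 4706 ± 933 (1.30 ± 0.14, adjusted p = 1.57e-04). Of the genes chosen after their values were seen, Alpl, the mineralizing phosphatase (0.78), and Spp1, osteopontin (0.67), rose, and the transcription factors Runx2 (0.14, adjusted p = 0.438) and Sp7 (0.29, adjusted p = 0.0994) did not pass. In all, 8 of 27 osteoblast genes were higher and 8 lower (9 and 9 adjusted over the list alone), with a median of -0.03 (-0.14 to 0.04 with any 1 library left out) and no list call (camera adjusted p = 0.638). The 8 higher became 3 without Control replicate 1, 4 without Control replicate 3 or Tfam cKO replicate 1 and 5 without Tfam cKO replicate 3, the 8 lower became 5 without Control replicate 1, and the adjusted p of Col1a1 rose to 0.0831 and that of Spp1 to 0.0539 without Control replicate 1, with 0.0526 for Spp1 without Control replicate 3.

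Of 14 osteocyte genes, 1 was higher and 1 lower (2 and 1 adjusted over the list alone). Cpz, a carboxypeptidase that binds Wnt proteins, fell from 153 ± 16.1 to 21.6 ± 11.7 normalized reads (-2.89 ± 0.28 SE, adjusted p = 6.38e-05), and Dpysl3, a cytoskeletal regulator, rose (0.72, adjusted p = 0.00726), while Ptprz1, a receptor phosphatase, did not pass (0.60, adjusted p = 0.0527). Dmp1 (0.32, adjusted p = 0.174) and Sost (-0.74, adjusted p = 0.167), markers of mature osteocytes chosen after their values were seen, did not pass either. The list was not called (camera adjusted p = 0.732), and its median of 0.20 (0.02 after quantile normalization, and 0.07 to 0.24 with any 1 library left out, lowest without Tfam cKO replicate 3) and mean of -0.04 differed in sign. Sost passed without Tfam cKO replicate 3 (adjusted p = 0.0326), and Ptprz1 passed without Control replicate 3 (0.0348) or Tfam cKO replicate 2 (0.0447) and with DESeq2 (0.0354).

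Among the signals that mesenchymal cells send to the bone-resorbing osteoclast, Csf1, a growth factor for osteoclast precursors and macrophages, rose from 160 ± 33.8 to 510 ± 83.2 normalized reads (1.68 ± 0.15 SE, adjusted p = 3.97e-05). Cxcl12, a chemokine that holds blood-forming cells in the marrow, fell from 2092 ± 212 to 636 ± 180 (-1.75 ± 0.16, adjusted p = 4.64e-05), and Wnt5a rose (1.25, adjusted p = 7.37e-04). Tnfsf11, which encodes RANKL, was at 40.0 ± 2.33 against 35.8 ± 9.43 (0.19, adjusted p = 0.632), and its decoy receptor Tnfrsf11b at 28.1 ± 3.60 against 28.9 ± 6.99 (-0.01, adjusted p = 0.977). In all, 3 of the 12 regulators were higher and 1 lower, also adjusted over the list alone, with no list call (camera adjusted p = 0.223). Of 22 osteoclast genes, 4 were higher and 1 lower (5 and 1 adjusted over the list alone), among them Mmp9, a gelatinase (0.70, adjusted p = 0.00541, but 0.13 and adjusted p = 0.517 after quantile normalization), Myo1d (0.56, adjusted p = 0.00451) and Snx10 (0.48, adjusted p = 0.0218), and the list did not pass (camera adjusted p = 0.0590). Acp5 (0.10, adjusted p = 0.681) and Ctsk (0.22, adjusted p = 0.297), the phosphatase and protease used as osteoclast markers and chosen after their values were seen, did not pass, and both turned negative after quantile normalization (-0.37 and -0.30). The 4 higher became 2 without Control replicate 2, Control replicate 3 or Tfam cKO replicate 3, where the Snx10 call ended (adjusted p = 0.0639, 0.0922 and 0.0914), and the 1 lower became 0 without any 1 library other than Tfam cKO replicate 2. The osteoclast list passed without Control replicate 1, Control replicate 3, Tfam cKO replicate 1 or Tfam cKO replicate 2. It also passed with all libraries, with no filter or at a mean of at least 5.

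A part of the cartilage genes was higher in Tfam cKO humeri, among them genes of the hypertrophic zone, where chondrocytes enlarge before bone replaces them. Of 11 hypertrophic genes, 7 rose and 0 fell, with the same counts adjusted over the list alone and a median log2 fold change of 0.63. Of the 7, Alpl and Ibsp are also on the osteoblast list and Vegfa on the hypoxia list. Col10a1, on chromosome 10, had 42.2, 129 and 39.8 normalized reads in controls and 1387, 682 and 709 in Tfam cKO (3.84 ± 0.37 SE, adjusted p = 6.38e-05), and the channel gene Panx3 rose from 94.5 ± 8.59 to 241 ± 43.0 (1.33 ± 0.14, adjusted p = 1.30e-04). The camera test gave an adjusted p of 7.58e-06, and adjusted p = 0.231 with an estimated correlation. Higher hypertrophic members numbered 5 without Control replicate 1, Control replicate 3, Tfam cKO replicate 1 or Tfam cKO replicate 3. Of 19 other growth plate genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 1.13. Comp, a matrix protein, rose from 37 reads over the 3 control libraries to 192 over the 3 Tfam cKO libraries (2.31 ± 0.33, adjusted p = 8.59e-04), 3110079O15Rik went from 3 reads to 36 (ratio 12.6, 95% counting interval 3.97 to 63.8), and Col11a2, a minor fibrillar collagen, fell from 3084 ± 60.2 to 1208 ± 168 (-1.36 ± 0.12, adjusted p = 2.87e-05). Col2a1, the main collagen of cartilage, chosen after its values were seen, was at 497 ± 159 against 427 ± 28.9 and did not pass (0.18, adjusted p = 0.555). The growth plate list passed the camera test at an adjusted p of 6.86e-04, and adjusted p = 0.445 with an estimated correlation. Its median was 1.39 with a pseudocount of 0.1 and 0.73 with 5. That median was 0.68 without Control replicate 3 and 0.69 without Tfam cKO replicate 1. Its lower members numbered 1 in place of 2 without Control replicate 1, Tfam cKO replicate 1 or Tfam cKO replicate 3. Its higher members numbered 5 or 6 with any 1 library left out.

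B lymphoid markers were lower throughout, in bones flushed of marrow. All 16 tested fell, also adjusted over the list alone, with a median log2 fold change of -2.49, or -2.43 with the 1 gene that reached 0 in a group at its bound. Pou2af1, a B cell coactivator, fell from 132 ± 45.5 to 18.4 ± 2.17 normalized reads (-2.73 ± 0.23 SE, adjusted p = 2.85e-05). The camera test gave an adjusted p of 1.07e-18, and adjusted p = 0.231 with an estimated correlation. Lower B lymphoid members numbered 13 without Control replicate 1. Erythroid markers fell less, 11 of 15 with none higher (13 and 0 adjusted over the list alone) and a median of -0.76, led by Ermap (-0.98, adjusted p = 0.00175). Their camera adjusted p was 1.17e-08, and adjusted p = 0.445 with an estimated correlation. Neutrophil and granule genes fell in 7 of 20 cases with none higher (11 and 0 adjusted over the list alone), with a median of -0.45, led by the transcription factor Cebpe (-1.01, adjusted p = 0.00500). Their camera adjusted p was 1.01e-06, and adjusted p = 0.445 with an estimated correlation. Macrophage and monocyte genes went the other way, with 7 of 18 higher and 1 lower (8 and 1 adjusted over the list alone), a median of 0.32 and C1qb, a complement subunit, rising from 64.0 ± 6.80 to 118 ± 18.1 (0.87, adjusted p = 0.00319). Their camera adjusted p was 0.010, and adjusted p = 0.445 with an estimated correlation. Lower erythroid members numbered 5 without Control replicate 1 and 7 without Tfam cKO replicate 1 or 3, and higher macrophage members 4 without Control replicate 2 or Tfam cKO replicate 3, while the 1 lower macrophage member became 0 without any 1 library other than Control replicate 2. Lower granule members numbered 1 without Control replicate 1 or Tfam cKO replicate 3, 2 without Control replicate 2, 4 without Tfam cKO replicate 1 and 13 without Tfam cKO replicate 2, and their median was -0.30 without Tfam cKO replicate 3.

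Markers of the other tissues that a dissected humerus can carry were not called as lists. Skeletal muscle genes varied between libraries within each group, with mean log2 values of 5.78, 8.55 and 7.21 in controls and 8.86, 7.80 and 5.94 in Tfam cKO. None of 25 passed, also adjusted over the list alone (camera adjusted p = 0.345), and the myosin Myh4 was at 166 ± 155 against 431 ± 423 normalized reads (adjusted p = 0.192), passing without Tfam cKO replicate 1 (adjusted p = 0.0360). Of 14 tendon and fibrous tissue genes, 1 was higher and 2 lower, with Dcn, the proteoglycan decorin, falling from 819 ± 135 to 260 ± 89.4 (-1.70, adjusted p = 2.86e-04). The list's median was 0.05 (-0.19 after quantile normalization, and from -0.44 without Tfam cKO replicate 1 to 0.38 without Tfam cKO replicate 3) and its test pointed down (camera adjusted p = 0.889). Of 18 endothelial genes, 2 were higher (0 without Control replicate 3 or Tfam cKO replicate 3, and 1 without either replicate 1) and 1 lower, with Stab2, a scavenger receptor of sinusoids, falling from 207 ± 33.2 to 51.2 ± 27.0 (-2.14, adjusted p = 0.00107), and the list's mean of -0.07 lay opposite to its median of 0.07 (-0.02 to 0.10 with any 1 library left out) and its test (camera adjusted p = 0.799). Of 13 adipocyte genes, 2 were higher and 3 lower (0 to 3 and 1 or 2 with any 1 library left out), with Fabp4 falling (-0.79, adjusted p = 0.00530; camera adjusted p = 0.799). None of 6 skin genes passed, with the smallest p for Sfn (-0.56, adjusted p = 0.399), and their median of 0.0017 (-0.17 to 0.47 with any 1 library left out) and mean of -0.02 differed in sign (camera adjusted p = 0.889). Of 11 nerve and glia genes, 0 were higher and 1 lower, Mbp, of myelin (-0.69, adjusted p = 0.0215), with a camera adjusted p of 0.799. Counts adjusted over the list alone were the same for these 5 lists after muscle. The Mbp call ended without Control replicate 1 (adjusted p = 0.0828), Control replicate 3 (0.101) or Tfam cKO replicate 3 (0.0848) and with DESeq2 (0.0716), muscle genes passed as a list without Control replicate 2 or Tfam cKO replicate 3, and tendon genes without Tfam cKO replicate 1.

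**Figure D2:**
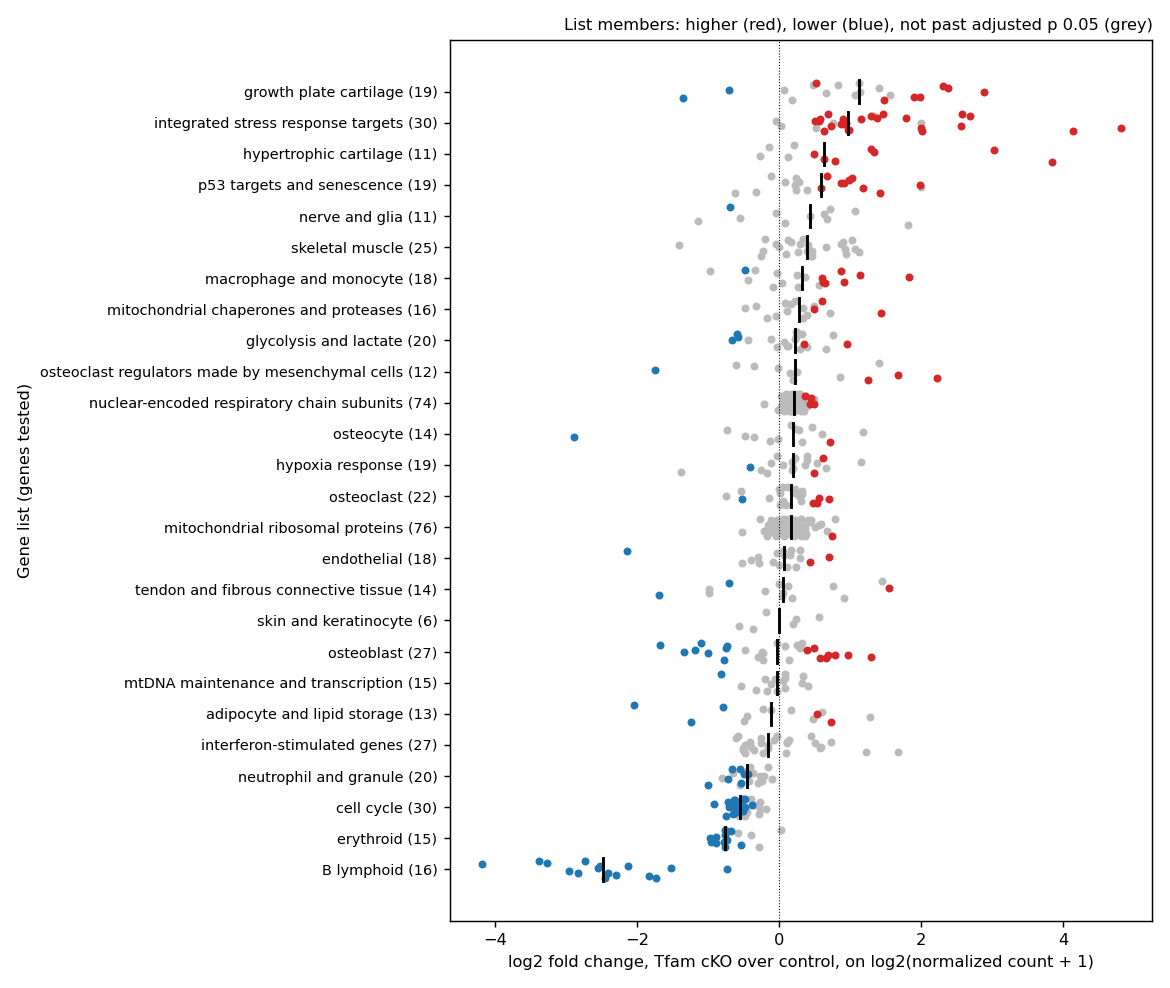
Log2 fold changes, Tfam cKO over control, of the members of 26 gene lists (each dot is 1 gene, coloured where its adjusted p is under 0.05), with a line at each list's median. B lymphoid genes lie lowest (median -2.49), cell cycle and erythroid genes are lower, and the stress response (0.98) and growth plate (1.13) medians lie highest. With a pseudocount of 5 the stress response and growth plate medians were 0.91 and 0.73. Osteoblast genes spread to both sides, with Col1a1 among the lower ones. Quantile normalization put Col1a1 at 0.02, but it gives all libraries the same highest values and so cannot show this fall.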

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

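The edgeR and DESeq2 fits to the recovered reads were chosen after seeing the data, though the plan named edgeR for a table of whole read counts. With 1 library left out, 891 to 1807 genes passed (545 to 834 higher, 346 to 973 lower) from fewer samples, and without Control replicate 1, 61.2% of calls were higher, against 51.6%. DESeq2 called 1138 (602 higher, 536 lower), and the cause was not tested. edgeR changed no call and no direction among the 90 named genes it tested. Every gene that any of these fits shared with the 1795 kept its direction. With the replicate block 1290 genes passed, 1267 of them among the 1795. The numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.43, 0.0055 and 0.14, and 1 of 3 controls correlated best with its own number. The remaining settings gave 1551 (the authors' deposited table) to 2061 genes (robust limma). Tfam stayed lower in every setting, at -0.94 to -0.57 with 1 library left out and -0.80 with DESeq2 (adjusted p = 0.0582, range over all settings 0.0198 to 0.107). With the correlation estimated per list 0 of 26 lists passed, against 12 to 14 in the other settings. Depth limits the genes with few reads most: a control count of 0 or 3 reads gives only a bound or a wide interval, as for Klk4 and 3110079O15Rik.

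After quantile normalization Col1a1 was at 0.022, Acp5 at -0.37 and Ctsk at -0.30. That method gives all libraries the same highest values, and Col1a1 and Col1a2 hold the 2 highest in 6 of 6 libraries, while for Acp5 and Ctsk the cause was not tested. With 1 library left out, log2 fold changes that had not passed crossed 0 for Tnfsf11 (-0.043 to 0.31), Tnfrsf11b (-0.22 to 0.13), Col2a1 (-0.073 to 0.33) and Acp5 (-0.016 to 0.18). Lists without a call that turned direction had adjusted p between 0.334 and 0.986 (interferon-stimulated), 0.0336 and 0.844 (tendon), 1.34e-05 and 0.652 (skeletal muscle), 0.591 and 0.986 (endothelial), 0.686 and 0.953 (adipocyte), 0.720 and 0.993 (skin) and 0.331 and 0.986 (nerve). The adipocyte list also turned at a mean of at least 5 (0.942) and the skin list with no filter (0.918). The cause was not tested.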

Other observations

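The tests on equal loss of marrow, on cell cycle genes, on the synthetases and on carried-over cartilage were chosen only after their results were seen in full or in part, and the 8 gene lists used here were added after seeing the data, as were the genes named from them and Prrx1. Genes of the lysosome were higher in Tfam cKO bone, with 15 of 30 higher and 0 lower and a median log2 fold change of 0.41. The cathepsin Ctsl rose from 199 ± 14.6 to 607 ± 39.7 normalized reads (SD, n = 3 each) and the peptidase Scpep1 from 110 ± 11.9 to 357 ± 32.5, and Gpnmb, a glycoprotein of lysosomes and phagocytes, from 37 reads to 255. Since these genes prompted the list, it was tested without them, and 13 of 28 were higher (camera adjusted p = 2.99e-10, and adjusted p = 0.184 with an estimated correlation). Macrophage and monocyte genes, whose cells are rich in lysosomal transcripts, were higher in the same libraries (mean log2 value higher by 0.32 ± 0.10, pooled SD). Of 22 osteoclast genes, 4 were higher and 1 lower (2 to 4 and 0 or 1 with any 1 library left out), and Acp5 (0.10) and Ctsk (0.22) did not pass. More macrophages could bring the rise of lysosomal genes, as could a change within mesenchymal cells, and both stay open. The stress response may also extend to cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation. Of 20, 10 were higher and 0 lower, including Sars (1.10) and Gars (0.71), and 0 of 17 mitochondrial synthetases passed either way. Without Sars, whose value had been seen, 9 of 19 were higher (camera adjusted p = 2.68e-05, and adjusted p = 0.184 with an estimated correlation).

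Prrx1, the mesenchymal transcription factor whose promoter names the Cre driver, rose from 154 ± 14.8 to 303 ± 21.4 normalized reads (log2 fold change 0.97 ± 0.11 SE, adjusted p = 2.31e-04). Megakaryocyte and platelet genes had a median of -0.79, with 2 of 13 lower and 0 higher (camera adjusted p = 3.69e-05, and adjusted p = 0.342 with an estimated correlation). Of 8 T and natural killer genes, 0 passed, and of 19 cholesterol synthesis genes, 0 were higher and 1 lower, Insig1 (adjusted p = 0.0475), with camera adjusted p of 0.919 and 0.439.

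B lymphoid markers fell in bones from which marrow had been flushed, so the amount of marrow left could differ between the groups. An equal loss of all marrow is argued against as the whole cause: the mean log2 value of B lymphoid genes minus that of granule genes was -2.64 ± 0.17 in controls and -4.65 ± 0.35 in Tfam cKO, a difference of -2.004. A smaller loss of marrow stays open, and cell cycle genes cannot be told apart from it, since their score minus the erythroid score differed by 0.13 (pooled SD 0.12), so they fell no more than erythroid genes did. A stromal niche with less support for B cell precursors may contribute: Cxcl12 fell, but of the 10 other niche factors 2 fell, Kitl (-0.88) and Vcam1 (-0.95), and 8 did not pass, among them Il7 (-1.17, adjusted p = 0.104), Flt3l (0.73, adjusted p = 0.125) and Foxc1 (0.32, adjusted p = 0.245), and the median of the 10 was -0.40, short of the bound of -0.5 set before. With Cxcl12, whose value had been seen, 3 of 11 niche factors were lower (camera adjusted p = 0.00108, and adjusted p = 0.163 with an estimated correlation). Less marrow left in the bones could lower these factors too, so a poorer niche cannot be told apart from it here. Whether the mutant bones lost B lineage cells is a biological difference that the genotype could bring, and these libraries do not test it.

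Of the cartilage genes, 7 of 19 growth plate members rose and 2 fell, and 7 of 11 hypertrophic members rose and 0 fell. Neither list passed camera with an estimated correlation (adjusted p = 0.445 and 0.231). More growth plate taken along with the Tfam cKO bones could produce the rises. For Col10a1 that is argued against as the whole cause, since Col10a1 minus Col2a1 was -2.80 ± 0.89 in controls and 0.86 ± 0.17 in Tfam cKO, a difference of 3.66. This takes Col2a1 alone as the measure of cartilage carried over. The growth plate list rose more than Col2a1, with a median of 1.13 (1.39 with a pseudocount of 0.1 and 0.73 with 5), against 3.84 for Col10a1. For the other cartilage genes it cannot be told apart from a change with the genotype: the 95% interval of Col2a1 reached 0.545, against 0.565, or 50% of the list's median, and it reached past 50% without Control replicate 3 (0.659 against 0.341), Tfam cKO replicate 2 (0.686 against 0.661) or Tfam cKO replicate 3 (0.706 against 0.591). Tfam cKO replicate 1 had the highest mean log2 value of growth plate genes (5.48, against 4.49 and 4.35 in the other Tfam cKO libraries), and without it Col2a1 was at -0.07. Skeletal muscle and tendon genes ranked the libraries in the same order within each group, muscle at 8.86, 7.80 and 5.94 in Tfam cKO. In controls, growth plate genes were at 3.48, 4.09 and 3.60 and muscle genes at 5.78, 8.55 and 7.21. Muscle values overlapped between the groups, and growth plate values did not. Tissue carried over in dissection could move both, which was not tested. More of the hypertrophic zone, whether from dissection or from a growth plate changed by the genotype, stays open and was not tested.

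Respiratory chain subunits had a median of 0.21, with 4 of 74 higher and 0 when adjusted over the list alone. Their camera adjusted p was 2.52e-07, and adjusted p = 0.445 with an estimated correlation. Of 27 large-subunit ribosomal proteins, 20 were higher (median 0.49, with Rpl12 at 0.81). Their camera adjusted p was 3.88e-16, and adjusted p = 0.163 with an estimated correlation. Both sets are short, with median exon lengths of 686.5 and 805 bases against 2867 over all tested genes, so a bias towards short transcripts could raise them. After each library's trend with length was removed, the medians were 0.11 and 0.34, or 53.6% and 69.8% of their values before, between the bounds set for and against, and the new fit called 1 and 15 genes higher, against 4 and 20. A length bias and a change with the genotype cannot be told apart here for these 2 lists. Respiratory chain subunits also ranked the libraries within each group as skeletal muscle genes did. Their mean log2 values were 7.02, 7.27 and 7.07 in controls and 7.35, 7.34 and 7.31 in Tfam cKO. Subunit values did not overlap between the groups, while muscle values did. Whether muscle carried over in dissection moved the subunits was not tested. The same correction took the median of mitochondrial ribosomal proteins (median exon length 1053 bases) from 0.16 to 0.11, or 65.6%, with 1 gene called higher before and 1 after.

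The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 1795 genes, more than any other (1 of the 10 splits), and the highest other gave 0. For the lists, 2 of the 10 splits gave as many as the real 12, the highest other giving 15, and the lowest of the others gave 3. Each of the 9 other splits mixes the genotypes unevenly. It puts much of their difference into the spread within groups and leaves part of it between them. The counts of genes and lists in those splits are therefore not a chance level.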
